A study of Mus musculus with 12 samples.

How the data were processed

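Poly(A)-selected RNA of cultured mouse pancreatic ductal adenocarcinoma cells was sequenced from 12 libraries, 6 of parental lines and 6 of the same lines after Cre. Per the labels' protocols, mRNA was captured with oligo(dT) beads from total RNA and converted to cDNA with random hexamer primers, and the protocol names no strand-marking step, so overlapping antisense genes cannot be told apart. The submitters' processing notes name FastQC 0.11.9, featureCounts, edgeR and the mouse builds GRCm38 and mm10. The aligner and the version of edgeR were not given in the sources used here.

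The deposited linear table holds a signal per gene for 20432 genes in 12 libraries. Each signal value is a read count divided by a scaled library size, in counts per 1e+06 reads (CPM below). Every value above 0 was a whole multiple of 1 step per library within a tolerance of 0.01 (100% of values in each library), so the read counts behind the deposited signal values were recovered by division. Scaling factors recomputed from these reads with edgeR's trimmed mean of M values (TMM) matched those in the file to within 5.90e-12. The recovered reads in genes ranged from 11.5 to 18.0 M (M, 1e+06 reads) per library, and 1 read was worth between 0.0569 and 0.0896 CPM. The second deposited table holds log2 values for 10903 of these genes. Its values lay closest to a log2 transform with a prior count of 2, its floor was -2.74, and the rule that chose its genes was not given in the sources used here.

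Gene identifiers were Entrez numbers. Symbols came from a RefSeq gene table of the GRCm38 assembly for 19448 genes and from GENCODE tables for 11 more, and 973 genes stayed unnamed, 244 of them among those tested. Coordinates are those of the RefSeq table on GRCm38.

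The following choices were made before the data were examined. Genes at or above 1 CPM, relative to the library's column total, in at least 6 libraries were tested, 12734 in all. Values were taken as log2(value + 0.5) and fitted with limma-trend (limma 3.58.1 in R 4.3.3) with cell line as a block and Cre against parental as the tested term, 2-sided. Adjusted p-values are Benjamini-Hochberg values over the genes tested, called under 0.05. A log2 change on this scale understates the change of low genes. Because a parental and a Cre library of 1 line form an isogenic pair in the series design, the block belongs to the main fit. In all 12 libraries the deviation from the group mean correlated best with that of the same line, with correlations across genes of 0.73 to 0.95 within pairs. Each line and condition has 1 library, so the p-values measure how alike the change was across lines.

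Of 28 fixed lists of genes, the 24 with at least 5 tested members were tested with camera from limma. The preset inter-gene correlation was 0.01, and p-values were adjusted over the 24 lists by Benjamini-Hochberg. The calls were repeated with an estimated correlation and with fry, which tests whether the genes of a list move on balance one way without comparing them with other genes. The mean change of a list per pair was also given an exact 2-sided sign-flip permutation test, whose smallest p with 6 pairs is 0.0313. Named genes were, by rule, of 3 kinds. They were the JAK and STAT family members, the 5 lower and 5 higher genes with the smallest p (fewer than 5 genes passed the adjusted threshold), and the 4 members with the smallest p from each list called by camera and from the interferon, MHC class I and STAT3 lists. Any other gene named was chosen after its values were seen.

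The gene test and the list test were tested on simulated data for the comparison of 6 pairs. Counts were drawn from the real means and library sizes, with 200 genes changed by the same fold in every line in each of 5 runs, over a median of 12623 genes. The share of changed genes recovered was 51.2% at 1.5-fold, 87.6% at 2-fold, 97.2% at 4-fold and 94.8% at 8-fold. Of 880 calls 53 were false, 6.02%. The real comparison called 3 genes, and the Benjamini-Hochberg cut on p is stricter where fewer genes are called. The shares recovered in these runs therefore do not carry over to the real comparison. A list of 30 genes shifted by -0.50 was called in 5 of 5 runs, and 0 of 95 lists that were not shifted were called. Simulated genes were drawn independently of each other, so these runs do not measure false calls for lists of correlated genes.

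The alternatives were other pseudocounts, filters and scalings, the deposited log2 table, no block, 3 other settings of limma's variance model and library weights, each pair left out, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads with the same block. Lists of acinar, endocrine, leukocyte and endothelial markers had too few tested members. The results of 1 called list and of some genes are not reported here, while counts of lists and members include them. Figures were drawn with matplotlib.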

Results

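The data are gene expression profiles of 6 mouse pancreatic ductal adenocarcinoma cell lines, named by the numbers 52205, 52419, 52424, 53105, 53369 and 53371. Each line was profiled as the parental culture, with wild-type JAK1, and again after infection with a retrovirus carrying Cre recombinase and a puromycin resistance gene and selection at 2, 4 and 7 µg/ml puromycin, a treatment meant to delete Jak1. JAK1 is a tyrosine kinase that passes signals from interferon and interleukin receptors to STAT transcription factors. The 6 parental and 6 Cre libraries held 11.5 to 18.0 M reads in genes. Cultures infected with an empty vector were not analysed here, so the effects of infection, selection and time in culture are part of every difference between Cre and parental cells.

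Jak1 itself, the targeted gene, was expressed at 170 ± 26.7 normalised counts per 1e+06 reads (CPM) in the parental libraries and 168 ± 44.2 in the Cre libraries (SD, n = 6 each). It lies on chromosome 4 from 101151974 to 101265282 (GRCm38), and each library held between 1358 and 3212 reads of it. The log2 change was -0.04 (SE 0.09), with a 95% confidence interval of -0.28 to 0.19, adjusted p = 0.838 by limma with Benjamini-Hochberg adjustment and exact sign-flip permutation p = 0.62, where 0.0313 is the smallest p that 6 pairs allow. It was lower in 4 pairs and higher in 2. A transcript that has lost some exons still gives reads from the others, and the labels do not say which exons Cre removes, so the gene total checks nothing about the deletion.

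The comparison of Cre with parental cells asks which transcripts change when JAK1 is deleted in established pancreatic cancer cells. The genes with the firmest change were receptors and a transcription factor of cytokine signalling. Osmr, the oncostatin M receptor subunit that pairs with gp130 in the interleukin-6 receptor family, fell from 10.3 ± 3.88 to 1.98 ± 1.12 CPM, a 4.61-fold lower level on the log2(value + 0.5) scale. Il13ra1, a subunit of the receptor for interleukins 4 and 13, fell from 27.7 ± 14.4 to 10.7 ± 5.63 CPM, and Cebpd, a C/EBP transcription factor of the acute-phase response, fell from 36.7 ± 9.52 to 13.3 ± 4.56 CPM (SD, n = 6 in each group). Each of the 3 was lower in 6 of 6 pairs.

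These 3 genes were the only ones past adjusted p under 0.05 among 12734 tested by limma with Benjamini-Hochberg adjustment. None was called higher, where 886 genes were higher at an unadjusted p under 0.05, edgeR called 0 higher and DESeq2 called 60. The log2 change of Osmr (chromosome 15, 6813568 to 6874968) was -2.21 (SE 0.21, limma adjusted p = 0.0181), that of Il13ra1 (chromosome X, 36112108 to 36171262) was -1.38 (SE 0.15, adjusted p = 0.0273) and that of Cebpd (chromosome 16, 15887286 to 15889545) was -1.48 (SE 0.17, adjusted p = 0.0273). At an unadjusted p under 0.05 there were 1928 genes, 1042 lower and 886 higher, which is 15.1% of those tested. Over the 31 other ways of swapping Cre and parental within pairs the highest such count was 1725. Of 100 drawn splits of all libraries 5, the real one included, reached 1928, with 2657 the highest. Some drawn splits keep the Cre libraries of the pairs they part on the same side, so they are not free of the Cre difference. In all 6 pairs 581 genes were lower and 523 higher, 8.67% of genes and 1104 together, against a median of 315 and at most 974 over the 31 other ways. On the recovered reads edgeR's quasi-likelihood test called 9 genes lower and DESeq2 called 211 lower, with Osmr, Il13ra1 and Cebpd among the calls of both tools. The limma count was 0 without the block, 0 with no filter on low genes, 34 with library weights, 0 without pair 52419, 52424 or 53369, 1 (Osmr) without 53105, 2 (Osmr and Il13ra1) without 53371 and 5 without 52205.

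**Figure D1:**
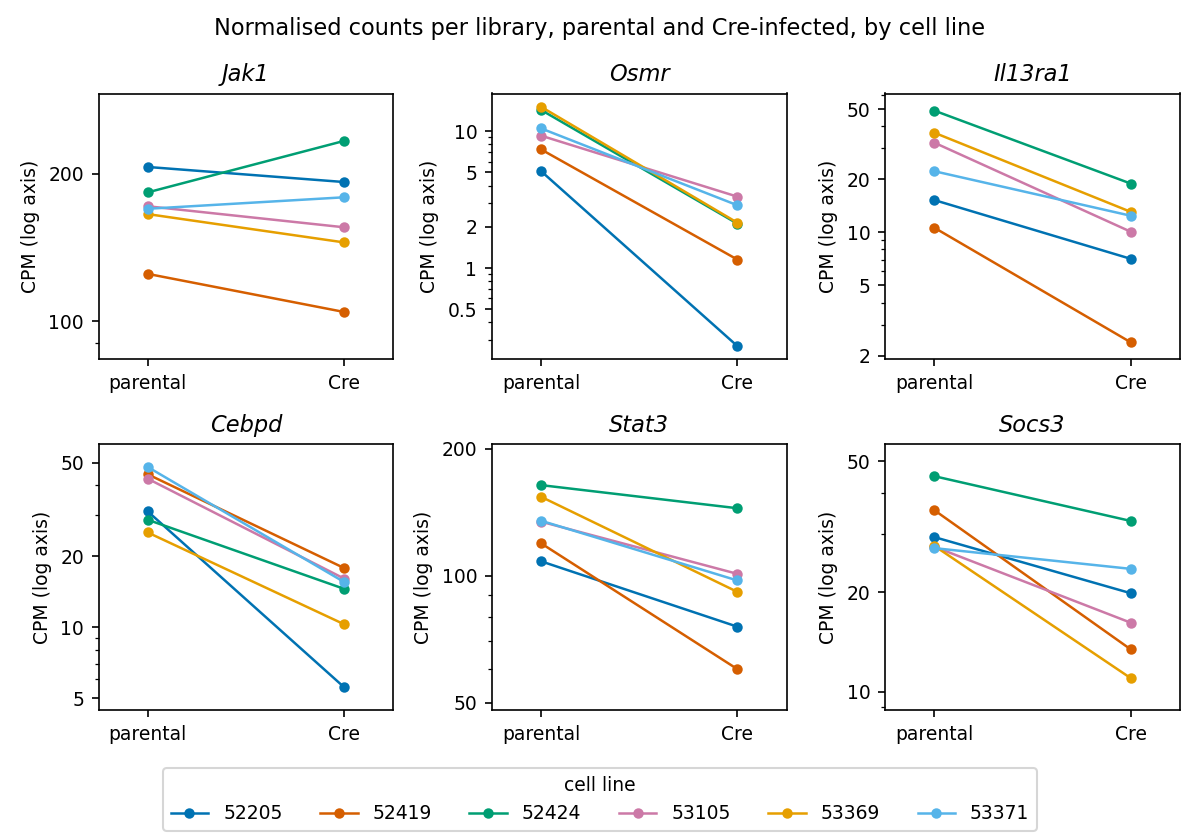
Normalised CPM (log axis) of Jak1, Osmr, Il13ra1, Cebpd, Stat3 and Socs3 in the parental and Cre library of each cell line, with 1 colour per line and a segment joining each pair. Osmr, Il13ra1, Cebpd, Stat3 and Socs3 are lower in 6 of 6 Cre libraries, and Jak1 is lower in 4 and higher in 2.

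Below the threshold, the next lower genes by p were Rasgrf1, a guanine nucleotide exchange factor, with a log2 change of -1.40 (limma adjusted p = 0.0586), and Thbs2, the matrix protein thrombospondin 2, with -1.21 (adjusted p = 0.0786, Benjamini-Hochberg), each lower in 6 of 6 pairs. Both were low in most lines. Rasgrf1 was at 11.1 CPM in parental 53369 and at most 4.83 in the other parental libraries. Thbs2 went from 2493 to 1163 CPM in 52419 and from 893 to 719 in 53369, and was at most 4.15 in the other parental libraries. The 5 higher genes with the smallest p did not pass either. Gclm, a subunit of the first enzyme of glutathione synthesis, was at 65.3 ± 12.6 CPM in parental and 89.3 ± 16.8 in Cre libraries, a log2 change of 0.45 (limma adjusted p = 0.0997). Impa1, an inositol monophosphatase, was at 0.36, Maoa, monoamine oxidase A, at 0.46, Arl14, a small GTPase, at 0.89 and Lrp2, the endocytic receptor megalin, at 1.22, each with limma adjusted p = 0.140 and higher in 6 of 6 pairs. Arl14 and Lrp2 had few reads in some lines. Arl14 went from 10 to 11 reads in 52419 and from 8 to 26 in 53369. Lrp2 had 6 reads in parental 53369 and 2 in parental 53371.

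The STAT3 target and acute-phase genes fell as a group. Of 26 measured members 22 had an estimate below 0, with a median log2 change of -0.41, and the mean of the list was lower in 6 of 6 pairs (-0.55 ± 0.14, SD over pairs). Beside Osmr and Cebpd, Socs3, the feedback inhibitor of JAK signalling, went from 32.1 ± 7.07 to 19.5 ± 7.97 CPM, a log2 change of -0.77 (limma adjusted p = 0.154), and Stat3 itself from 136 ± 20.7 to 95.1 ± 28.6, a change of -0.55 (adjusted p = 0.137, Benjamini-Hochberg), both lower in 6 of 6 pairs. Over all genes tested 2 members passed, both lower. Adjusted over the list alone 10 passed as lower and 1 as higher, the survival gene Mcl1 (0.22). Among the 10 were the secreted lipocalin Lcn2 (-2.36), the complement component C3 (-1.31), Socs2 (-0.79) and Bcl3 (-0.65). In line 52205 Lcn2 changed by -5.48, against -2.95 to -0.39 in the other lines, and C3 by -4.08. The camera adjusted p was 6.30e-09 with Benjamini-Hochberg adjustment over 24 lists, and adjusted p = 0.0228 with an estimated correlation, the only list called that way. It was also called by fry (adjusted p = 0.000248).

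Receptors and kinases of the same pathway were lower as lists, mostly through few members. Osmr, Stat3 and Il4ra also belong to the STAT3 list, so the calls of these lists are not separate from it. Among 9 measured interleukin-6 family cytokines and receptors, 5 had an estimate below 0 and 4 above. Osmr passed the test, and Lif (-0.33), Il11ra1 (-0.25) and Lifr (-0.14) did not. The median of that list was -0.10 (camera adjusted p = 0.0449, and adjusted p = 0.275 with an estimated correlation), -0.20 to -0.073 over the pairs left out in turn, and fry called it at adjusted p = 0.0437. Il11ra1 was at -0.14 without pair 53371 and Lifr at -0.024 without 52419. The camera call was lost without pair 52205 or 52419 (adjusted p up to 0.105). Among 9 other JAK1-coupled receptors Il13ra1 passed, and its partner Il4ra, at 153 ± 82.4 CPM in parental and 103 ± 49.7 in Cre libraries, had a change of -0.55 (limma adjusted p = 0.177), passed when adjusted over the list alone and was called lower by DESeq2. The interferon receptor subunits Ifnar2 (-0.28) and Ifnlr1 (-0.26, and -0.17 without pair 52205) did not pass. The median of these receptors was -0.16 (camera adjusted p = 0.00595, and adjusted p = 0.275 with an estimated correlation). With each pair left out in turn the list stayed called, with a median between -0.18 and -0.046.

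Of the 10 measured JAK and STAT family members, Jak1 included, 8 had estimates below 0, and 0 passed limma over all genes, where 4 were lower at an unadjusted p under 0.05. Stat3 and Jak3 passed adjusted over the list alone and were the members called by DESeq2, and edgeR called 0. Jak3 was at -0.68 (limma adjusted p = 0.155, 6 of 6 pairs lower), Stat2 at -0.58, Jak2 at -0.26, Tyk2 at -0.05, Stat6 at -0.01, Stat5a at 0.13 and Stat5b at 0.19. Without pair 52419 Stat2 was at -0.31, Jak2 at -0.14, Stat5b at 0.092 and Tyk2 at 0.052, and without pair 53105 Stat5a was at 0.044 and Stat6 at 0.013. The list had a median of -0.16 and a camera adjusted p of 0.0281 (adjusted p = 0.503 with an estimated correlation), and without pair 52419 the median was -0.074 and the call was lost.

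Interferon-stimulated genes, which interferons induce through JAK1, were lower as a list at the preset correlation, with very different sizes between lines. They were not called with an estimated correlation (adjusted p = 0.503) or by fry (adjusted p = 0.277). Of 34 measured members 31 had an estimate below 0 and the median log2 change was -0.60. The list mean changed by -2.14 in line 52419 and by -0.93 in line 53369, and by -0.05 to -0.30 in the other 4 lines. Ifitm3, a membrane protein that restricts viral entry, was at 142 ± 186 CPM in parental and 59.5 ± 82.8 in Cre libraries, a log2 change of -0.95 (limma adjusted p = 0.140), and passed when adjusted over the list alone. Ifit1 was at -1.15, Ifi27 at -1.32 and Irf9, a DNA-binding interferon regulatory factor, at -1.08 (24.7 ± 21.4 against 9.14 ± 1.40 CPM), or -0.71 without pair 52419. Over all genes limma called 0 members and edgeR 0 of these 34, while 15 were lower at an unadjusted p under 0.05 and DESeq2 called 6 lower, Ifitm3, Ifit1, Ifi27 and Irf9 among them. Ifi44, an interferon-induced gene below the filter and named after its values were seen, was called lower by edgeR (adjusted p = 0.0362), from 24.2 to 0.231 CPM in line 52419 and from 8.41 to 0.50 in 53369. The camera adjusted p was 2.22e-08 at the preset correlation, and the median was -0.28 without pair 52419.

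MHC class I antigen presentation genes were also lower as a list. Of 15 measured members 11 had an estimate below 0 with a median of -0.18 (camera adjusted p = 0.0355, and adjusted p = 0.503 with an estimated correlation). Psme1, a proteasome activator subunit, was at -0.29, Nlrc5, the transactivator of MHC class I genes, at -0.62, the class I gene H2-Q4 at -0.44 and the peptide transporter gene Tap2 at -0.47. None of the members passed limma over all genes or adjusted over the list alone, 3 were lower at an unadjusted p under 0.05, and edgeR and DESeq2 called 0. H2-Q4 belongs to a family of near-identical genes whose reads the counting could split, so its value is uncertain. Without pair 52419 or 53369 the list was no longer called, with adjusted p up to 0.148. The median was -0.26 to -0.090 over the pairs left out in turn, and the list mean was not lower in line 52205 (0.066).

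Cell-cycle genes were higher, by far the most in a single line. All 40 E2F and mitotic genes had an estimate above 0, with a median log2 change of 0.61 (camera adjusted p = 3.19e-15, and adjusted p = 0.503 with an estimated correlation). Limma called 0 of them over all genes or adjusted over the list alone, and edgeR and DESeq2 called 0, while 25 were higher at an unadjusted p under 0.05. The list mean changed by 2.20 in line 53371, by 0.77 in 52424, by 0.33 in 52205, by 0.32 in 52419, by 0.15 in 53369 and by -0.09 in 53105 (exact sign-flip permutation p = 0.0625, n = 6 pairs). Mcm2 and Mcm5, subunits of the replicative helicase, were at 0.60 and 0.75, Rrm2, a subunit of ribonucleotide reductase, at 1.04 and Cdc20, an activator of the anaphase-promoting complex, at 0.65. Without pair 53371 the median was 0.27, with Mcm5 at 0.45, Rrm2 at 0.61 and Cdc20 at 0.38. MYC and ribosome biogenesis genes had a median of 0.16 over 32 members (camera adjusted p = 2.38e-05, and adjusted p = 0.503 with an estimated correlation), with Bop1 at 0.32, Nolc1 at 0.27 and Nop2 at 0.24, while Myc itself was at -0.29 and lower in 6 of 6 pairs. Limma, edgeR and DESeq2 called 0 of these 32, and 5 were higher and 1 lower at an unadjusted p under 0.05. The list mean was not higher in line 53105 (-0.22) or 52424 (-0.0045), and with each pair left out the list stayed called, with a median from 0.096 without 53371 to 0.25 without 53105.

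**Figure D2:**
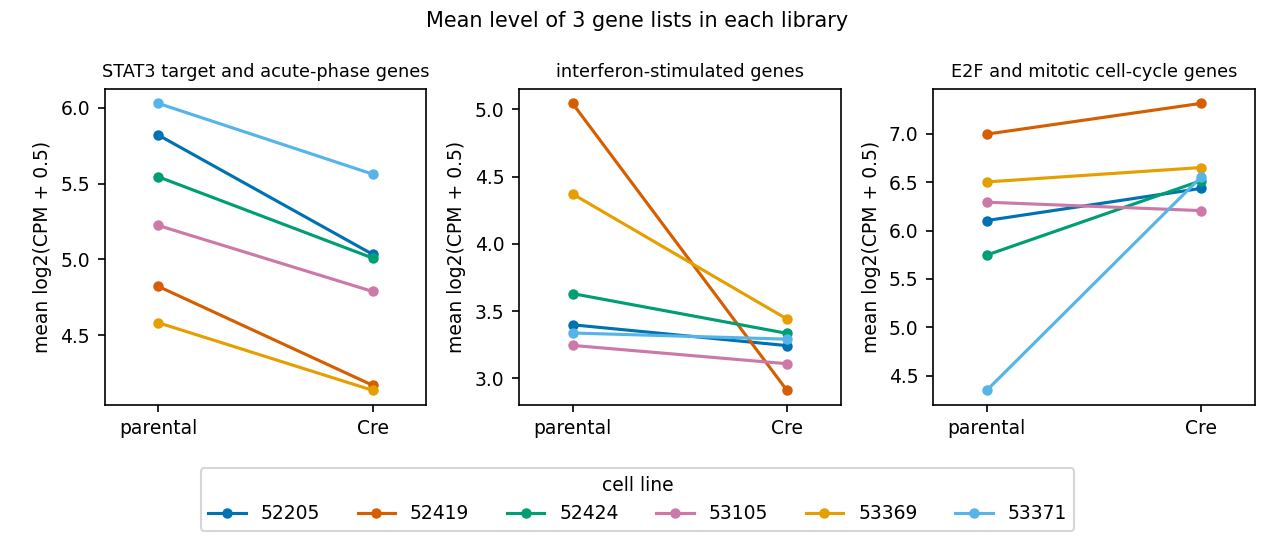
Mean log2(CPM + 0.5) of the STAT3 target and acute-phase genes, the interferon-stimulated genes and the E2F and mitotic cell-cycle genes in the parental and Cre library of each line, with 1 colour per line. The STAT3 list is lower in each Cre library, the interferon list changed by -2.14 in line 52419, and the cell-cycle list of parental 53371 is the lowest of the 12 libraries, at 4.35.

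NF-kB target, stress and hypoxia genes were lower as lists. NF-kB target genes had a median of -0.12 over 22 members (camera adjusted p = 0.0355, and adjusted p = 0.275 with an estimated correlation), with Ier3 (-0.64) lower when adjusted over the list alone, Bcl3 at -0.65, Birc3 at -0.32 and Csf1 at 0.46, and the call was lost without pair 52205 or 52424 (adjusted p up to 0.157). The mean of that list was not lower in line 53371 (0.014). Unfolded-protein and ATF4 stress genes had a median of -0.29 over 25 members (camera adjusted p = 0.000923, and adjusted p = 0.503 with an estimated correlation). Among them Aldh1l2 was at -0.94, the cystine transporter Slc7a11 at -0.58, Vldlr at -0.56 (-0.32 without pair 52419) and Ddit4 at -0.48 (-0.25 without 52424). None of the 25 passed limma over all genes or adjusted over the list alone, 7 were lower at an unadjusted p under 0.05 and DESeq2 called Aldh1l2, and the list mean was higher in lines 52205 (0.14) and 52419 (0.26). Hypoxia and glycolysis genes had a median of -0.20 over 28 members (camera adjusted p = 0.00706, and adjusted p = 0.503 with an estimated correlation), with Ero1a at -0.75 (past the test when adjusted over the list alone), Adm at -1.03, Bnip3 at -0.68 and P4ha2 at -0.46, and its mean was higher in line 52205 (0.11). Without pair 52424 neither the stress list (median -0.091) nor the hypoxia list (adjusted p = 0.0715) was called, and the hypoxia median was -0.27 to -0.13 over the pairs left out.

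Of the lists on the state of the tumour cell, basal-like subtype genes and fibroblast markers were lower. Basal-like genes had a median of -0.24 over 12 members (camera adjusted p = 0.0355, and adjusted p = 0.503 with an estimated correlation), with the integrin gene Itgb4 (-0.85) and the epidermal growth factor receptor ligand gene Areg (-0.51) lower when adjusted over the list alone, and Slc2a1 at -0.24 and Dhrs9 at -0.38. This call was lost without pair 52205 or 52424 (adjusted p up to 0.304), with a median of -0.32 to -0.15 over the pairs left out. The list mean was higher in lines 53105 (0.11) and 53371 (0.13) and lowest in 52205 (-0.70) and 52424 (-0.67). The 5 measured fibroblast and stellate-cell markers had a median of -0.45 (camera adjusted p = 0.0355, and adjusted p = 0.275 with an estimated correlation) and were lost without pair 52205, 53105 or 53369 (adjusted p up to 0.0934), with a median of -0.43 to -0.26 over the pairs left out and a higher list mean in line 52424 (0.27). Pdgfra, a growth factor receptor of mesenchymal cells, was at 45.2 ± 60.5 CPM in parental and 25.1 ± 31.4 in Cre libraries, a log2 change of -0.71 (limma adjusted p = 0.0786). It was called lower by edgeR (adjusted p = 0.0305) and by DESeq2. Ly6c1 was at -0.58 and Col3a1 at -0.45 (-0.97 without pair 52424), while Col1a1 was at 0.13 and turned to -0.13 with library weights and to -0.040 without pair 53105.

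The remaining 10 lists were not called by camera over the 6 pairs. Their adjusted p-values and median log2 changes were 0.0726 for chemokines and inflammatory cytokines (median -0.33), 0.0697 for mesenchymal genes (-0.091), 0.123 for classical pancreatic cancer subtype genes (0.12), 0.265 for ductal and progenitor genes (-0.22), 0.273 for TGF-beta targets (-0.095), 0.311 for epithelial genes (-0.19), 0.628 for YAP and TEAD targets, 0.653 for p53 targets (-0.0060), 0.656 for cholesterol biosynthesis genes (-0.022) and 0.786 for the BCL2 family (-0.054, and -0.083 to -0.0085 over the pairs left out). The YAP and TEAD list had a median of 0.11 and a mean of -0.01. With 1 pair left out 6 of the 10 lists were called. These were chemokines without 53371 or 53369 (camera adjusted p down to 0.00417), mesenchymal genes without 52424 (0.0020), classical genes without 52419 (0.0174), epithelial genes without 53371 or 53105 (down to 0.0271), and TGF-beta targets (0.0440) and ductal genes (0.0449) without 53369. Their medians over the pairs left out ran from -0.43 to -0.17 for chemokines, -0.20 to -0.011 for mesenchymal, 0.036 to 0.17 for classical, -0.19 to -0.014 for TGF-beta and -0.35 to -0.094 for ductal genes. Of the lists too small to test, Cela1 of the acinar genes, 0 endocrine genes, Cd14, Fcgr3 and Cd68 of the leukocyte markers and Kdr and Flt1 of the endothelial markers passed the filter, and 0 of them were called by limma or edgeR.

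**Figure D3:**
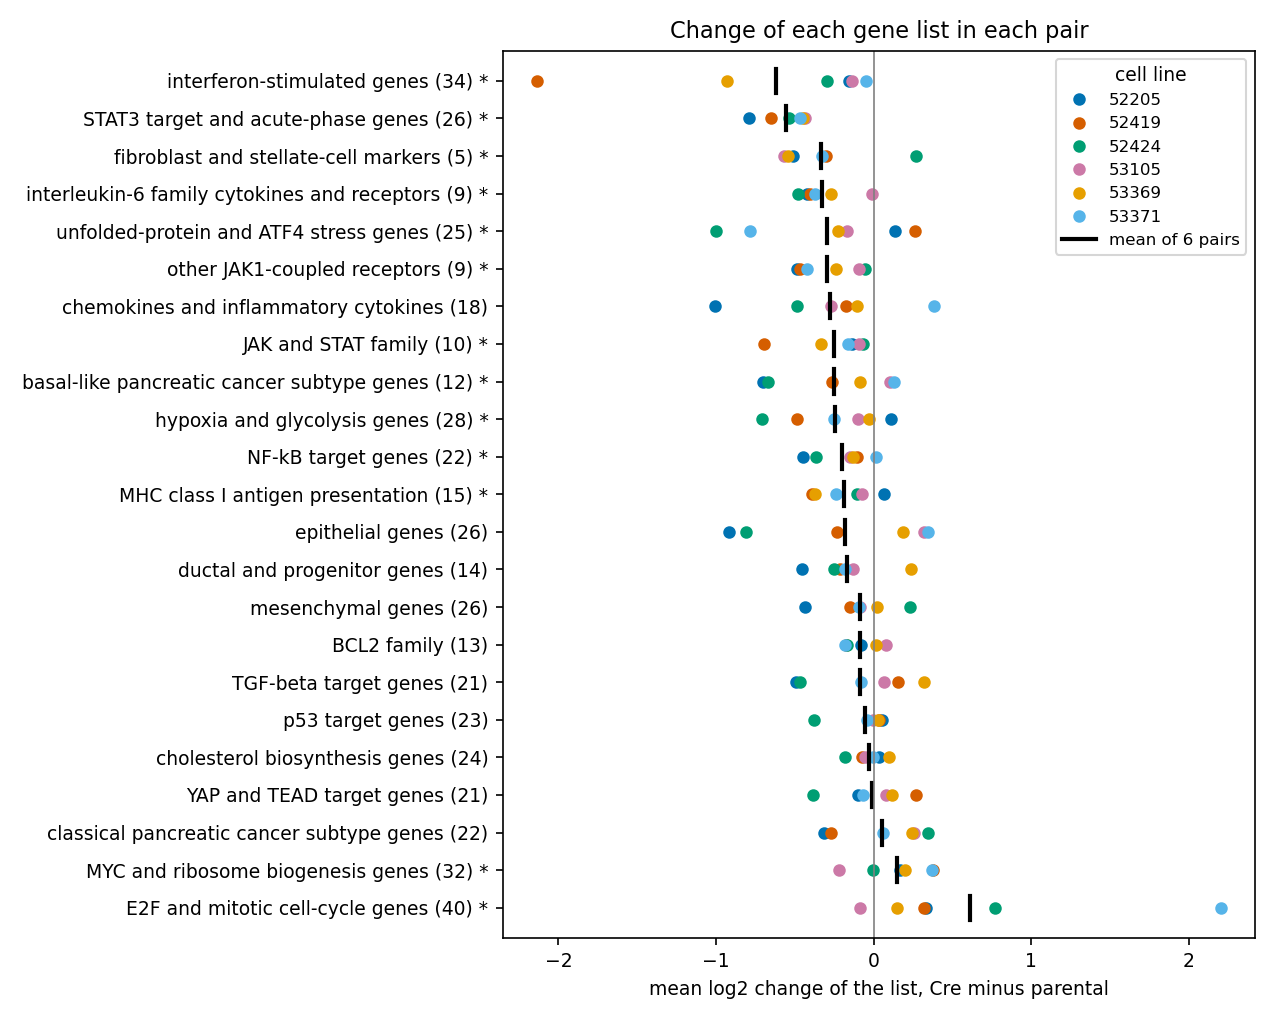
Mean log2 change (Cre minus parental) of each gene list reported here in each pair, with 1 coloured point per cell line, a black bar at the mean of the 6 pairs, the number of measured members in parentheses and an asterisk at lists with a camera adjusted p under 0.05 at the preset correlation. The STAT3 list lies between -0.44 and -0.79 in the 6 pairs, and the E2F list between -0.09 and 2.20.

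By camera at the preset correlation 12 lists were called lower and 2 higher, and 10 lists were called without the block. Of the 14 lists called with the block only the STAT3 list was called with an estimated correlation and 3 were called by fry, with fry adjusted p of 0.0706 to 0.401 for the other 11. With the exact sign-flip permutation test 6 lists reached the smallest p that 6 pairs allow, 0.0313, which is 0.125 after Benjamini-Hochberg adjustment over 24 lists. Differences between the lines were far larger than the difference between Cre and parental cells, with 90.9% of the summed variance between lines, 2.77% between Cre and parental and 6.32% residual. These shares are not divided by degrees of freedom, so they do not rank the Cre difference below the residual. Counting genes that differed over 2-fold within a pair, at 10 CPM or more, gave 641 in line 53371, 490 in 52424, 290 in 52205, 190 in 52419, 99 in 53105 and 84 in 53369, with 1 library on each side and no replicate check.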

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

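The sign-flip test over 6 pairs was planned for every list, and its use to weigh a shared rise of the cell-cycle list was chosen only after the result was seen, as was every choice of which value to weigh. For each of 92 sets of 6 values (library sizes, list changes and named genes), the highest or lowest value was set against the others, and it counted as standing apart when its gap to the nearest value, as a share of the range, exceeded Dixon's 95% critical value. In 9 of the 92 sets a value stood apart, where chance gives about 4.6. The sets are not independent, because named genes such as Cdc20 and Col3a1 also belong to the lists. The chance count also assumes normally distributed values, so the 9 is not a measured excess.

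The cell-cycle list changed by 2.20 in line 53371 against -0.09 to 0.77 in the other 5 pairs, and Cdc20 changed there by 2.01 against 0.15 to 0.79. Mki67, a proliferation marker, went from 25.8 to 249 CPM in that line, Birc5 from 8.66 to 94.7 and Top2a from 103 to 569, and the parental library had a list level of 4.35 against 5.75 to 7.00 in the other parental libraries. The 20 genes of a quiescence list, written before it was tested, changed by -0.44 in line 53371, below the -0.30 to 0.15 of the other pairs. A parental culture of 53371 that cycled more slowly when it was harvested would give this value. Faster cycling of its Cre culture would lower these genes too, so the list cannot separate these causes. In 52424, with the next largest cell-cycle change (0.77), the quiescence list changed by -0.0066. A rise shared by the pairs stays open, because the exact sign-flip permutation test over 6 pairs gave p = 0.0625, and the mean over the 5 other pairs was 0.30 ± 0.31 (SD). With 1 library per line and condition, an effect of Cre on that line and the state of its parental culture cannot be told apart.

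Other values stood apart as follows. The parental library of 53105 held 18.0 M reads in genes, against 11.6 to 13.2 M in the other parental libraries. The p53 target list changed by -0.38 in line 52424, against -0.04 to 0.05 elsewhere. Fibroblast and stellate-cell markers changed by 0.27 in line 52424, against -0.57 to -0.30, and Col3a1, a fibrillar collagen on that list, changed there by 2.15, against -1.36 to -0.56. Tyk2 changed by -0.57 in line 52419, against 0.01 to 0.16. Maoa changed by 0.044 in line 53105, against 0.43 to 0.65. Nop2 changed by -0.27 in line 53105, against 0.24 to 0.44.

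Chance was weighed against the number of calls by regrouping the libraries. Among 100 drawn splits of the 12 libraries into 6 and 6, 5 gave at least as many genes as the real 3. The real one is among these 5, and the other 4 each gave 409 and are 1 and the same fit. They part pairs 52424 and 53371 alone, with the Cre libraries of both on the same side. With cell line as a block, that fit compares the Cre with the parental libraries of these pairs. It therefore contains their Cre difference, so the count over drawn splits cannot decide whether chance gave the real 3. Among the 32 splits that part every pair, as the real one does, 1 gave as many genes, the real one, and the highest other was 0. This is the smallest share that 32 splits can give. The real split thus stood above all others there, but chance is not excluded. For lists 1 of 100 and 1 of 32 splits, the real one each time, gave 14, with 13 the highest other in both. The real count was the highest but close to the next, and some drawn splits repeat the same fit. Chance is therefore not excluded for the count of 14 lists. The median over the other splits was 7 lists among the 100 and 6 among the 32, so chance is not excluded for any single list by this count.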

How the results depend on the processing

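All alternatives below were chosen before the data were examined. The count of genes called, 3 with the settings used, was 0 with no filter, 0 with no replicate block (pairing ignored), 34 with library weights (33 lower, 1 higher), 9 by edgeR and 271 by DESeq2 (211 lower, 60 higher), and 2 or 3 under the other 8 settings of limma and the scaling. The cause was not tested, except that leaving out the pairing puts the variance between lines into the error. Leaving out each pair in turn gave 0 to 5 genes, 10 to 16 lists and a Jak1 change of -0.12 to -0.0019. Of the 17 alternatives fitted with limma, Osmr passed in 12, Il13ra1 in 10 and Cebpd in 8, and edgeR and DESeq2 each called all 3. The log2 change of Osmr ran from -2.52 to -1.61 over all 17, and its adjusted p from 0.0165 to 0.0898 over the pairs left out. The count of lists, 14, was 1 with an estimated correlation and 3 by fry, and 10 to 14 under the other alternatives with all pairs.

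With library weights Col1a1 was at -0.13 and the list medians of p53 (0.0044), BCL2 (0.041), cholesterol (0.029) and TGF-beta genes (0.0093) changed sign. The direction of the BCL2 test also reversed with no replicate block, at a median of -0.054, and that of the epithelial test without pair 52424, at a median of -0.11. Over the pairs left out Tyk2 ran from -0.094 to 0.052, Stat6 from -0.031 to 0.013 and Col1a1 from -0.040 to 0.40. List medians ran from -0.040 to 0.061 for p53, from -0.063 to 0.033 for cholesterol, from -0.024 to 0.15 for YAP and TEAD and from -0.30 to -0.063 for epithelial genes. Under the alternatives 355 list results kept their direction and side of the threshold, 57 lost a call, 11 gained 1 and 9 reversed. Of the results on named genes 1060 kept both, 21 lost a call, 9 gained 1 and 4 reversed. With 1 read worth 0.0569 to 0.0896 CPM, depth limits mainly genes near 1 CPM.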

Other observations

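The test of read number for the Rosa26 transcript, and the correlations of the interferon list, were chosen after the result was seen. The genes in this part were chosen after their values were seen. The lines differed widely in epithelial state. Cdh1, E-cadherin, was at 0.37 CPM in parental 52419 and 17.5 in parental 53369, against 272 to 805 in the other 4 parental lines, and the mean log2 level of the epithelial list was 1.0 and 2.13 in these lines, against 4.18 to 7.46. The transcription factor Gata6 was at 5.80 and 4.21 CPM in 52419 and 53369, against 33.4 to 48.8 in the others, while the mesenchymal list was highest in the same lines, at 6.0 and 6.33. The surface protein gene Epcam differed between Cre and parental cells in opposite ways, from 79.3 to 11.1 CPM in 52205 and from 366 to 127 in 52424, but from 69.2 to 100.2 in 53371, with no replicate check of any single pair.

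Genes below the filter used for the test, or outside the named set, were called lower by edgeR. Crabp1, a retinoic acid binding protein, went from 124 to 24.4 CPM in 52419 and from 606 to 124 in 53369, and was below 1 CPM in the other lines. Dmp1, a mineralised matrix protein, went from 133 to 21.0 and from 34.7 to 5.64 CPM in the same lines. The secreted WNT regulators Dkk3 and Dkk2 were also called, Dkk2 from 375 to 126 CPM in 52419 and from 477 to 172 in 53369.

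The non-coding transcript of the Rosa26 locus, Gt(ROSA)26Sor (chromosome 6, 113067428 to 113077244, GRCm38), was higher in 3 Cre libraries and not in the other 3. It went from 3.15 to 25.5 CPM in 52205, from 3.37 to 111 in 53369 and from 2.84 to 88.2 in 53371, and from 9.96 to 8.53 in 52419, 4.74 to 4.80 in 52424 and 6.77 to 5.46 in 53105. The tables argue against a change of the whole region, since the neighbours Setd5 and Thumpd3 were higher by at most 0.22 on the log2 scale in these 3 lines, and against counting noise, since the fewest reads among the 3 Cre libraries were 285. A candidate explanation is Cre recombination of an engineered allele at this locus in these lines, but the labels name no such allele, a response to infection and selection in some lines stays open, and no biological explanation was tested.

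Interferon-stimulated genes fell by different amounts between lines. The parental list level ran from 3.24 to 5.05 over the 6 lines and the Cre level from 2.91 to 3.44, with Irf7 going from 44.2 to 1.08 CPM in 52419. Members near the floor could have produced this, but over the 13 members at 10 CPM or more in all parental libraries the spread of the changes was 0.792 of that over the whole list, from -1.67 to -0.02, so low counts are not the whole cause. Over the 6 lines the change had a Spearman correlation of -0.943 with the mean of the parental and Cre levels (exact permutation p = 0.0167). The correlation with the parental level had the same value, and Pearson correlations with both were also computed. Each is partly built in, with the parental level because the change contains it. With the mean, a negative value tends to follow where the Cre levels vary less than the parental ones, as they did here. The correlations therefore cannot decide whether lines with a higher interferon tone fall further. Without 52419 and 53369 the Pearson correlation with the mean went from -0.888 to -0.674, and these are also the lines with the least Cdh1, so other differences between the lines stay open.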
